A study of Felis catus with 38 samples.

How the data were processed

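Total RNA from oral tumour biopsies of pet cats was sequenced. The labels give 2 time points, Day 1 before treatment and Day 8 under CS3D, with 19 libraries each. The tissue was crushed in liquid nitrogen and lysed in a bead mill, and RNA was purified on columns with DNase digestion, per the labels' protocols. Library preparation and sequencing were done by a company, per the same source. The labels also give a batch. All Day 1 libraries and 11 Day 8 libraries, with numbers from 1 to 12, were batch 1, and 8 Day 8 libraries, with numbers from 13 to 20, were batch 2.

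The values are whole-number read counts per gene and library, in the count table the authors deposited, with no normalisation. HISAT2 2.0.5 and featureCounts are named in the submitters' processing notes. The genome build, the annotation release, the strand setting and the treatment of reads shared between similar genes are not given in the sources used here, so overlapping genes and near-identical copies cannot be separated from one another. The table holds 26681 gene IDs, of which 23589 had a count in at least 1 library. The files do not pair these IDs with gene symbols, and 0 of them could be matched to a symbol with the reference table used here. For that reason the gene lists fixed before the data were examined, the values of STAT3 and a correction for keratinocyte and muscle markers could not be computed, and no gene is named by symbol.

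Genes were filtered with filterByExpr at its default minimum count of 10, which left 14996 genes holding 99.8% of all counts. Counts were scaled by TMM and tested with edgeR 4.0.16, using the robust quasi-likelihood test in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights) were alternatives. The log2 CPM values used outside the models had a prior count of 2. The design fixed before the data were examined had batch and day as terms and no block. Other settings chosen beforehand were fits with the replicate number as a block, with and without batch, other scalings and filters, both other tools and fits within the numbers that share a batch label. The comparisons of numbers 13 to 20 with 1 to 12, and their interaction with day, were also fixed beforehand.

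The labels give the same numbers at both days without stating that a number is a cat. The pairing was therefore checked, before the calls of the fits were compared, on the correlation of deviations from the mean of each day over the tested genes. All 19 pairs had r above 0.1, from 0.365 to 0.882 (median 0.634), against a median of -0.0519 between different numbers. From Day 1, 19 of 19 libraries correlated best with their own number, and from Day 8, 18 of 19. The numbers were taken to pair the biopsies, and a number is called a cat in the text. No libraries were duplicates, since the smallest chi-square per degree of freedom among 703 pairs of libraries was 20.0. The fit with the block and without the batch term, also chosen beforehand, is reported as a result of its own. Its other settings, the gene modules, the tests between disjoint sets of cats, the main axis between cats, the order of columns and the account of cat 3 were chosen after seeing the data. Exploratory fits, including limma's voom without quality weights, preceded them. The share of reads of the 3 most abundant genes was not fixed beforehand either.

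Gene modules were made by k-means on standardised log2 CPM, averaged over both days for each cat, for 13266 genes with a mean log2 CPM of at least 1. The number of modules was 12, and 8 and 20 were also tried. The change of a module was the mean of its genes' Day 8 minus Day 1 differences in each cat. Such changes were tested by flipping their signs over cats, two-sided, with 100000 draws for 18 or 19 cats and exactly for 11 or 8. The main axis between cats was the first principal component of the same cat averages. Repeated fits used 100 drawn splits, or 60 drawn swaps of the days within cats. The number of swaps was lowered from 100 for running time after a first run had been seen.

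The rule for named genes took the largest changes past the threshold with a mean log2 CPM of at least 1 and the same direction in at least 12 cats, first from the fixed design and then from the fits with the block. Its requirement of a symbol could not be met and was dropped, and 2 IDs per direction are printed. The procedures were tested on simulated counts for 14996 genes with a dispersion of 0.1 and 100 genes changed at each size. At log2 changes of 1 and 2, the fit with the block and without batch recovered 100% and 100% with 13 false calls. The fit with block and batch recovered 89% and 100% with 6 false calls, and the fit with batch and no block 50% and 93% with 1 false call. With no gene changed, the fit with the block and without batch made 0 calls, with 688 genes at an unadjusted p under 0.05. Each simulated gene was drawn independently with the same dispersion, whereas the real changes were shared among genes and uneven between cats. False calls under such changes were therefore not tested. Recovery was not tested at smaller changes, such as the median log2 of 0.59 of the genes called higher below. The module test found a planted shift of 0.4 in 20 of 20 draws and passed no module in 20 draws without one. The shift was planted in 1 module, whose real change had an SD of 0.21 over cats. It was larger than the falls of modules reported below, so power for those was not tested. The draws were sign flips of the real changes, the same operation as the test, so few passes were built in. Total counts ranged from 10.6 to 22.6 M per library, where M is 1000000 counts. At these depths a gene of 1 CPM rests on few reads, and its changes are less precise than those of abundant genes.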

Results

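Gene expression was measured in biopsies of oral tumours from 19 pet cats, each sampled at Day 1 before treatment and at Day 8. The Day 8 libraries are labelled with CS3D, a cyclic oligonucleotide directed at the transcription factor STAT3, and the study's design text places that biopsy before the treatment given on the day. No untreated cats were sampled at Day 8 in the libraries used here, so time, repeated biopsy and treatment are one contrast. Total counts, in M counts of 1000000 each, averaged 16.6 ± 4.09 M at Day 1 and 15.5 ± 2.79 M at Day 8 (SD, n = 19 each). The paired difference was -1.11 ± 3.60 M, higher at Day 8 in 8 of 19 cats (permutation p = 0.197). Between 16687 and 19062 genes had a count in each library.

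Libraries of the same number resembled each other more than those of different numbers, which is the ground on which a number was taken to be a cat. The values below therefore describe that pairing and are no separate evidence for it. Same-numbered libraries also stand in the same part of the count table, which may add to their resemblance. The deviations of the Day 1 and Day 8 libraries from the mean of their day correlated with r from 0.365 in cat 7 to 0.882 in cat 1, across genes, which are not independent replicates. The highest correlation between different cats was 0.498. The share of variance between cats had a median of 0.610 over the tested genes and exceeded 0.5 in 70.2% of them. The Day 8 library of cat 7 was the exception in matching, with r = 0.388 to the Day 1 library of cat 17.

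**Figure D1:**
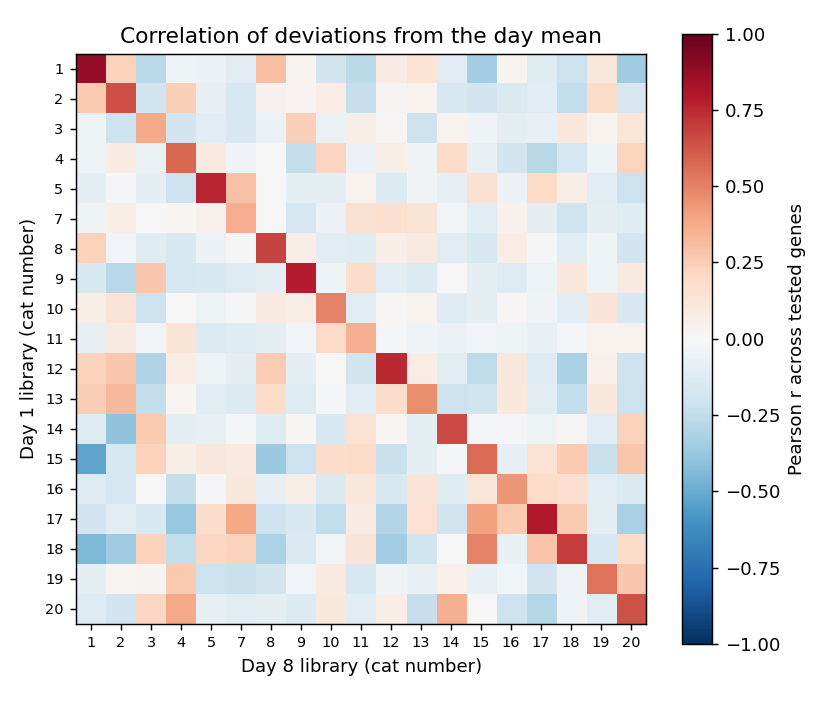
Pearson r across the tested genes between each Day 1 library (vertical axis, cat number) and each Day 8 library (horizontal axis, cat number), after subtraction of the mean of the day. The diagonal holds the 19 same-numbered pairs, from 0.365 to 0.882, and the highest value off the diagonal is 0.498.

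The comparison of Day 8 with Day 1 asked which genes changed in the tumours between the pre-treatment biopsy and the biopsy a week into the trial. With the cat as a block and no batch term, 767 genes were higher and 290 lower at Day 8. The higher genes had a median log2 change of 0.59, a 1.51-fold rise, and 102 of them rose more than 2-fold. The lower genes had a median of -0.58, and 81 of them fell more than 2-fold. Of the higher genes, 668 moved in the same direction in at least 15 cats and 20 in all 19, and of the lower genes 236 and 0. Leaving out 1 cat moved the lower count by more than 1.5 times for 6 cats, to 148 without cat 5, 154 without cat 11, 163 without cat 17, 167 without cat 15, 171 without cat 20 and 193 without cat 7. The higher count was 500 without cat 20, where the total was 671, and the totals were 674 without cat 11 and 683 without cat 5. For the same design DESeq2 called 1286 higher and 857 lower, or 60.0% higher against 72.6%, and limma 941 higher and 450 lower. In edgeR the counts were 556 higher and 168 lower without the low-count filter, and 920 higher and 498 lower with log2 library total as a covariate.

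The 4 most abundant genes that rose included the 3 with the most reads of the table. Those 3 together took 3.13 ± 3.43% of the reads at Day 1 and 7.25 ± 5.88% at Day 8 (SD, n = 19). Their share was higher at Day 8 in 16 of 19 cats, by 4.13 ± 3.71 percentage points (permutation p = 5.0e-05). In the 11 cats whose biopsies were both labelled batch 1 the difference was 3.69 ± 4.19 points, higher in 9 (exact p = 0.00684). In the 8 cats whose label changed to batch 2 it was 4.73 ± 3.08 points, higher in 7 (exact p = 0.0156). The cut at 3 genes was not fixed beforehand, and the next most abundant gene did not rise, so the p-values of this share do not allow for that choice. All 3 genes belonged to module 1, so their share and the rise of that module are not independent results. In edgeR's test with the cat as a block, the log2 changes of these 3 genes were 1.42 ± 0.27, 1.16 ± 0.24 and 1.30 ± 0.25 (SE), with adjusted p = 0.00625, 0.00790 and 0.00625. The ninth most abundant gene rose by 1.04 ± 0.20 (adjusted p = 0.00620), in 17 of 19 cats. In the same test 0 of the 10 most abundant genes were called lower, but some were lower in most cats. The fourth most abundant gene changed by -0.49 ± 0.38, lower in 17 cats (adjusted p = 0.432). The seventh changed by -1.10 ± 0.42, lower in 14 (adjusted p = 0.106). The 10 genes with the most reads in a library took 10.0 ± 3.38% at Day 1 and 13.6 ± 5.42% at Day 8, higher in 15 of 19 cats (permutation p = 0.00101).

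Among genes called in that fit, ENSFCAG00000010245 had the largest rise, with a log2 change of 2.20 ± 0.63 (SE). It went from 1.31 ± 2.90 CPM to 5.81 ± 7.30 CPM (SD, n = 19), was higher in 15 cats and had an adjusted p of 0.0384. ENSFCAG00000043019 rose by 2.18 ± 0.51, from 3.26 ± 6.92 CPM to 8.18 ± 14.4 CPM, in 15 cats (adjusted p = 0.0152). The largest fall was that of ENSFCAG00000042595, with a log2 change of -2.77 ± 0.76, from 49.7 ± 106 CPM to 5.85 ± 14.4 CPM, lower in 16 cats (adjusted p = 0.0322). ENSFCAG00000045246 had a log2 change of -2.30 ± 0.55, from 8.82 ± 15.6 CPM to 1.00 ± 1.37 CPM, lower in 13 cats and higher in 5 (adjusted p = 0.0180). Some of these numbers of cats rest on few reads. ENSFCAG00000042595 went from 1 to 0 reads in cat 9 and from 2 to 1 in cat 18, while it had 424 CPM at Day 1 in cat 4 and 210 CPM in cat 7. ENSFCAG00000010245 went from 0 to 2 reads in cat 2. The files do not pair the 4 IDs with symbols. In limma with the same block and no batch, the log2 changes of these 4 genes were 1.89, 1.27, -2.80 and -2.66. With block and batch the log2 changes of these 4 genes were 1.41, 1.85, -3.42 and -1.88, with adjusted p of 0.345, 0.198, 0.0994 and 0.150. With batch and no block the log2 changes were 0.11 ± 0.75 and 0.07 ± 0.85 (SE) for the first pair, against 2.20 and 2.18 above, and -2.67 ± 1.29 and -2.54 ± 1.06 for the second, with adjusted p of 0.998, 0.998, 0.763 and 0.750. That fit sets the Day 8 libraries of cats 1 to 12 against the Day 1 libraries of all 19 cats, so these are not changes within cats. With the block, the log2 change of ENSFCAG00000010245 was 1.43 in cats 1 to 12 and 3.18 in cats 13 to 20, and that of ENSFCAG00000042595 was -3.44 and -1.56, and -0.65 in cats 14 to 20. The call of ENSFCAG00000010245 was also lost without any 1 of cats 7, 8, 10, 11, 12, 14, 15, 18 and 20, and that of ENSFCAG00000042595 without any 1 of cats 4, 11, 13, 15 and 17.

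**Figure D2:**
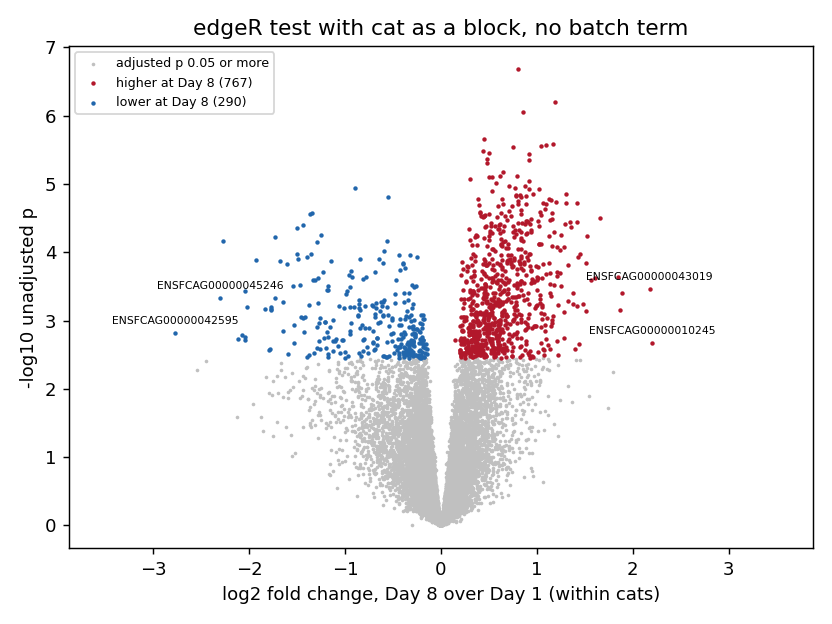
Log2 change from Day 1 to Day 8 within cats (horizontal axis) against -log10 of the unadjusted p (vertical axis) for each tested gene, from edgeR's quasi-likelihood test with the cat as a block and no batch term. Red points are the 767 genes called higher, blue points the 290 called lower and grey points the others, and the 4 IDs given in the text are marked.

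These calls depended on the terms of the model. The design fixed beforehand, with batch and no block, called 0 genes in edgeR's test, with 975 of 14996 at an unadjusted p under 0.05, and DESeq2 and limma also called 0. Without batch or block the count was 0, with 1400 at an unadjusted p under 0.05. With both the block and batch, edgeR called 0 genes, with 2686 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0683, and DESeq2 called 725. With the block, only cats 13 to 20 change label, so the batch term leaves the day effect to cats 1 to 12. The fits with and without batch therefore share these cats, and agreement between them is not independent. All 1057 genes called with the block and no batch had the same sign with block and batch, where 979 had an unadjusted p under 0.05. Their median log2 change in size was 0.59 in both fits, while the median standard error was 0.14 without and 0.19 with the batch term. With batch and no block, 1042 of them had the same sign, with a median size of 0.45 and a median standard error of 0.30. With the block, edgeR called 0 genes in cats 1 to 12 alone, with 2360 at an unadjusted p under 0.05, and 0 in cats 13 to 20 alone, with 1801. Scaled by library totals in place of TMM, which moved the median log2 change of all genes to -0.11, 31.7% of 1814 called genes were higher, against 72.6% of 1057.

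The change was also measured between sets of cats that shared no animal. Only the 14570 genes tested in both sets and in all cats were used. The 2322 of them with an unadjusted p under 0.05 in cats 1 to 12 moved in the same direction in cats 13 to 20 for 89.0%, by a mean log2 of 0.36 ± 0.26 in that direction (SD, 8 cats), in 7 of 8 (exact sign-flip p = 0.0156). The 1782 genes selected in cats 13 to 20 moved in the same direction in cats 1 to 12 for 91.0%, by 0.42 ± 0.42 (SD, 11 cats), in 10 of 11 (exact sign-flip p = 0.00195). Across the 14570 genes, which are not independent replicates, the log2 changes of both sets correlated with Pearson's r = 0.598 and Spearman's rho = 0.539.

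Groups of genes that varied together between cats changed by unequal amounts. Module 1, of 1452 genes, rose by a mean log2 of 0.44 ± 0.36 (SD, n = 19), in 16 of 19 cats. It held 581 of the 767 higher genes, or 75.7%, and 0 lower ones, and the abundant genes that rose belonged to it. Module 10, of 988 genes, changed by -0.35 ± 0.55 and was higher in 3 cats. Module 8, of 1023 genes, changed by -0.22 ± 0.31 and was higher in 4, and module 3, of 1295 genes, changed by -0.09 ± 0.16 and was higher in 6. In permutation tests adjusted over 12 modules, p was 0.00072 for module 1, 0.00732 for module 10, 0.0246 for module 8 and 0.0361 for module 3. Modules 2 and 9 did not pass, with adjusted p of 0.0765 and 0.0897, although module 9 held 63 of the lower genes. With any 1 cat left out, modules 1, 8 and 10 passed in 19 of 19 cases and module 3 in 10, the pass being lost without cat 3, 4, 5, 7, 10, 11, 15, 17 or 18, with adjusted p up to 0.0689. Module 2 passed without cat 9 or 19, module 9 without cat 2 and module 12 without cat 7.

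In cats 1 to 12, module 1 rose by 0.48 ± 0.42 in 9 of 11 (exact p = 0.00586), and in cats 13 to 20 by 0.40 ± 0.28 in 7 of 8 (exact p = 0.0156). Module 10 changed by -0.43 ± 0.68 in the first set (exact p = 0.00684) and by -0.22 ± 0.28 in the second (exact p = 0.0781). Cat 3 alone changed by -2.30 in module 10, and without it the first set changed by -0.25 ± 0.29 (SD, 10 cats, exact p = 0.0137) and all cats by -0.24 ± 0.28. The second set's module 10 had an exact p of 0.0312 without cat 14. Module 8 changed by -0.19 ± 0.34 (exact p = 0.0928) and -0.26 ± 0.28 (exact p = 0.0469), and module 3 by -0.11 ± 0.18 (exact p = 0.0537) and -0.06 ± 0.11 (exact p = 0.156). The size of the change of module 3, and the side of 0.05 on which the exact p of module 8 lay, depended on single cats. With any 1 cat left out, module 8 stayed between -0.13 and -0.24 in the first set and between -0.20 and -0.33 in the second. Module 3 changed by -0.07 in the first set without cat 3 and by -0.04 in the second without cat 15, and its exact p in the first set was 0.0352, 0.0195 and 0.0449 without cat 1, 9 or 12. Module 8 had an exact p of 0.0371 in the first set without cat 8, and in the second set 0.0625 to 0.0938 without any 1 cat other than cat 14. Scaled by library totals, 8 modules passed in place of 4, module 1 higher with 0.36 ± 0.32 and the others lower. Module 9 changed by -0.07 ± 0.37 in the first set (exact p = 0.588) and by -0.31 ± 0.24 in the second, lower in 7 of 8 (exact p = 0.0156), and module 2 by 0.18 ± 0.27 (exact p = 0.0332) and 0.04 ± 0.17 (exact p = 0.555). With 1 cat left out, module 9 in the first set ranged from -0.12 without cat 2 to 0.01 without cat 7. Module 2 in the first set was 0.12 (exact p = 0.0664) without cat 3, with an exact p of 0.0645 to 0.0664 also without cat 4, 5, 10 or 12, and in the second set it ranged from 0.0025 without cat 17 to 0.07 without cat 19. The difference between the sets had an exact permutation p of 0.130 for module 9, 0.198 for module 2 and 0.521 for module 10, and of 12 modules none passed, with a smallest adjusted p of 0.771. The modules were defined on the same libraries, and no gene symbols were at hand to describe their members.

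**Figure D3:**
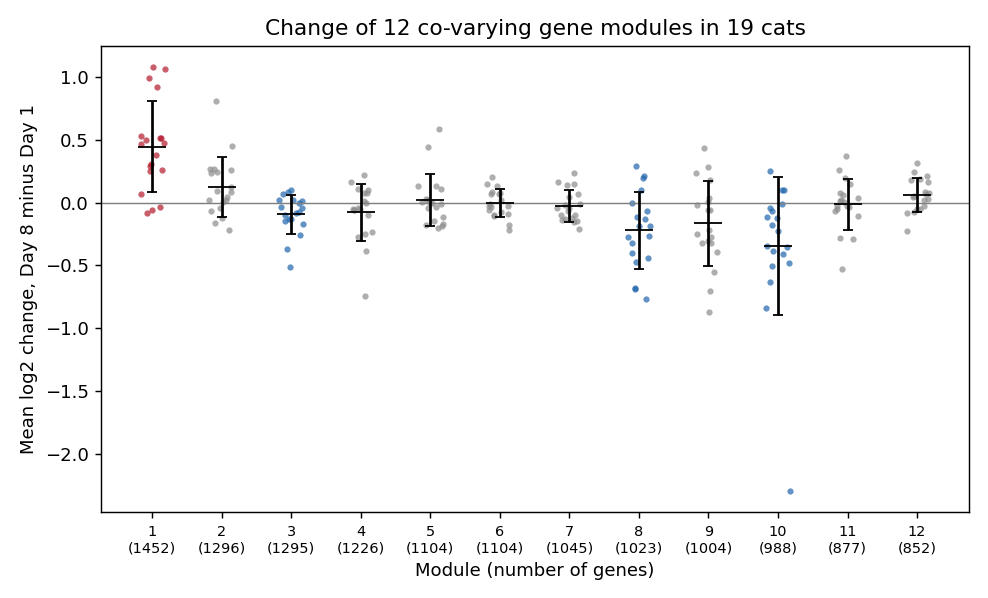
Mean log2 change from Day 1 to Day 8 (vertical axis) of 12 gene modules (horizontal axis, with the number of genes in brackets), 1 point per cat, with the mean and SD over 19 cats as bars. Module 1, in red, was higher in 16 cats, and modules 3, 8 and 10, in blue, were higher in 6, 4 and 3, while modules in grey did not pass the test.

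The change between days was set against the batch label by comparing cats 13 to 20 with cats 1 to 12. The difference between their Day 8 changes passed for 0 genes in edgeR's test, with 74 at an unadjusted p under 0.05, and for 0 with the cat as a block, with 399, and DESeq2 called 0. With the block, this difference is the same term as batch, so a batch effect and a difference between the sets cannot be told apart there. At Day 8, where these cats carry different batch labels, 0 genes differed in edgeR's test, with 1826 at an unadjusted p under 0.05, against 162 in DESeq2. At Day 1, where all libraries carry one label, 0 genes differed, with 2085 at an unadjusted p under 0.05, against 79 in DESeq2. A result that misses the threshold does not show that the sets were alike.

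The depth followed another division of the cats. In the count table, libraries of cats 1 to 13 stand before those of cats 14 to 20. Which of these divisions, that of the batch label or that of the columns, follows the sequencing runs is not given in the sources used here, so the batch term may not describe the runs. At Day 1 the totals averaged 12.0 M in cats 14 to 20 and 19.3 M in cats 1 to 13, a difference of -7.28 M (exact permutation p = 1.98e-05, the smallest that 50388 splits can give). At Day 8 the difference was -4.04 M (exact permutation p = 0.000913). Between these sets of cats, edgeR called 164 genes at Day 1, with 81 higher and 83 lower in cats 14 to 20, and 11 at Day 8. Without the low-count filter the count at Day 1 was 48. Within the sets, the test of Day 8 against Day 1 with the cat as a block called 0 genes in cats 1 to 13 and 29 in cats 14 to 20, of which 2 were higher.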

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

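Alternatives of the fit within cats, of the modules and of the comparison of cats 14 to 20 with 1 to 13 were chosen after seeing the data. For Day 8 against Day 1 with batch and no block (0 genes), the count was 1 without a low-count filter, 1057 with the replicate block and no batch term, 725 in DESeq2 with block and batch, and 0 in all 11 others. For the 1057 genes of the fit with the block, the counts were 2143 in DESeq2, 1814 with library totals, 29 in cats 14 to 20 alone, and 0 with a batch term, in cats 1 to 12, 13 to 20 or 1 to 13 alone, or with the main axis score as a covariate. The subsets hold fewer cats. With the block, the batch term leaves the day effect to cats 1 to 12, so that fit is in effect such a subset, with larger standard errors. The log2 changes of the 4 IDs were 1.41, 1.85, -3.42 and -1.88 with the batch term. In cats 1 to 12 alone they were 1.43, 1.87, -3.44 and -1.90. The cause of the other differences was not tested. Leaving out 1 cat gave 671 to 1166 genes, with 671 without cat 20, 674 without cat 11 and 683 without cat 5. The other settings gave 724 to 1418. Under library totals, of the called genes outside the 100 most abundant 30.8% were higher, a balance that follows from the shift of all genes and decides nothing about dilution as its source. With log2 library total as a covariate the median size of the 1057 changes was 104% of its value. The 4 IDs kept their direction in every setting run and lost the call in 16, 6, 13 and 4 settings (ENSFCAG00000045246 did not pass the count filter in the settings without a value). For cats 13 to 20 against 1 to 12, DESeq2 gave 162 and no filter 2 at Day 8, and 79 and 1 at Day 1, against 0, and the interaction was 0 in all settings. For cats 14 to 20 at Day 1, no filter gave 48 against 164. Library totals gave 8 modules against 4, leaving out 1 cat 3 to 5, and the other settings 3 to 6. Besides Day 8 against Day 1, only the interaction was run with and without the replicate block, with 0 in both. The planned gene lists and the correction for keratinocyte and muscle markers were not run, for lack of symbols.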

Other observations

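The tests of the labelled batch, of dilution on the higher and lower genes, of the main axis, of the totals of cats 14 to 20 and of cat 3, the gene modules and the split counts of comparisons with 0 calls were chosen after the results were seen. The test of the balance of higher and lower calls was first written for the calls themselves and was assigned to the balance after its value was seen.

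The changes differed in size between cats. The SD of the log2 change over genes was 1.56 in cat 3, followed by 1.06 in cat 11, with a median of 0.748 and a lowest value of 0.429 in cat 1. In cat 3, 63 genes of at least 100 CPM at Day 1 fell at least 32-fold, 46 of them in module 10. The fourth most abundant gene of the table went from 14389 to 5.30 CPM in that cat, while the 3 most abundant ones were higher there at Day 8. Falls of this size numbered 29 in cat 16, 13 in cat 13 and 11 in cat 7, and 10 of the 13 and 11 of the 11 lay in module 8. Of the 29 in cat 16, 0 lay in module 8, 1 in module 10, 6 in module 9 and 22 elsewhere. The modules were made from averages that include Day 8, so a large fall in 1 cat can itself draw genes into the same module. These counts per module are therefore partly built in. In the other 18 cats the median log2 change of the 63 genes in each cat averaged -0.37 ± 0.50 over cats, lower in 12 (permutation p = 0.00638). The Day 8 library of cat 3 had the fewest genes with a count, 16687.

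For the genes called between days within cats, 1 of 60 drawn swaps of days, the real days, gave as many as 1057 genes, and the highest of the others gave 1. Chance as the source is thereby argued against, but 60 swaps cannot show a p below 1 in 60. A difference between the labelled batches as the whole cause is argued against by the genes selected in cats 13 to 20, which moved by 0.424 in the same direction in cats 1 to 12, whose biopsies share one batch if the labels are right. Dilution by a few abundant genes was also examined for the higher genes. Under library totals, 551 of 744 such genes outside the 100 most abundant were still called higher, so those 551 rose even as a share of all counts. The higher genes were selected for rising after TMM, however, and even the smallest rise among them was 0.15. That exceeds in size the common shift of -0.11 that library totals leave in, so the outcome followed largely from the selection and decides little about dilution. The 10 genes with the most reads in a library took a larger share at Day 8 in 15 of 19 cats, so dilution need not have run the same way in all. The lower genes had a median of -0.58 (quartiles -1.10 and -0.31), below the common shift of -0.11 that library totals leave in. They were selected for falling after TMM, which removes that shift, and even the smallest fall among them was -0.14. The outcome thus followed from the selection and decides nothing about dilution for the lower genes. A shift of the biopsies along the main axis of difference between cats was measured, by 25.5 ± 27.6 units in 16 of 19 cats (permutation p = 0.00034) and by 21.0 ± 19.2 units in 15 of 18 without cat 3 (permutation p = 0.00045), but the score is made from the same expression values, so the fall of the median size to 44.8% with the score as a covariate follows from that shift and decides nothing. Composition of the biopsy, response to treatment and healing of the first biopsy stay open, since there are no untreated cats or gene symbols here.

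For the lower depth of cats 14 to 20, the labelled batch is argued against, since the Day 1 libraries share one label and differed with an exact permutation p of 1.98e-05, but that rests on the label being right, which the division of depth and columns on both days leaves in doubt. Of 100 splits of the cats, 1, the real one, gave as many as the 164 genes at Day 1, and the highest of the others gave 47. For a division given in advance this argues against chance, with no p below 1 in 100 possible. The division was taken up after seeing the data, which neither the splits nor the permutation p allow for, so chance is not excluded. A separate sequencing or extraction run, whether or not the label records it, or a difference between the cats, stays open and was not tested.

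For cat 3, a swapped Day 8 library is argued against by its correlation of 0.376 with its own Day 1 library, above the highest with any other Day 1 library, 0.267. A biopsy of other tissue content and a response of this cat stay open, and no biological explanation was tested.

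For Day 8 against Day 1 with batch and no block, and for cats 13 to 20 against 1 to 12 at Day 8, at Day 1 and in the interaction, the real count was 0. All 100 of 100 splits reach such a count, so the number of called genes decides nothing about chance there. The highest of the other splits gave 418, 393, 716 and 0 genes, and the larger of these point to a structure of differences between cats. At an unadjusted p under 0.05, 42 of 100 splits had as many as the 975 genes of the real days, 12 as many as the 1826 at Day 8, 3 as many as the 2085 at Day 1 and 75 as many as the 74 of the interaction. The splits behind the 42 ignore the pairing and can leave both biopsies of a cat on one side, whereas swaps of days within cats, in the fit with the block and no batch, gave at most 2280 such genes against 3721 for the real days.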
